A study of Synechocystis sp. PCC 6803 with 8 samples.

How the data were processed

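The series measured RNA of the cyanobacterium Synechocystis on 8 one-colour Agilent arrays. The strains were wild type (WT) and a mutant (Δcph2) that lacks Cph2, a photoreceptor of the phytochrome family encoded by sll0821. Per the labels, cultures were kept for 48 h in blue or green light at 5 µmol photons, in medium with 11 mM glucose and 10 mM TES buffer. The design text says that 2 biological replicates of each strain and light were hybridised, so each of the 4 groups holds 2 arrays. It also says that blue light raised the second messenger c-di-GMP in WT and not in the mutant, with no difference in green light, which served as the control.

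Per the file headers, the scanner files hold the spot intensity in arbitrary units, as read by Feature Extraction 10.7.3.1, with a mean and a median signal, a local background and a background-subtracted processed signal for each spot. The deposited value table holds log2 intensity. Its values had the same rank order as the median spot signal (rank correlation 1) and a common distribution on every array, so the authors' table was read as quantile-normalised log2 of the median signal without background subtraction. The submitters' processing notes credit limma for that step. The table served as an alternative here. The names of the deposited files place the 4 arrays of each light on 1 slide, so light and slide cannot be told apart. The strain comparisons within a light lie within 1 slide.

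Each array carried 42303 spots, of which 1417 were controls. The other 40886 spots held 20363 probes for 8830 features: coding genes, antisense RNAs (as), RNAs internal to genes (int), untranslated regions (UTR), intergenic transcripts (NC) and tRNA or rRNA. The processed signal was taken as log2, and each array's 75th percentile over non-control spots was subtracted. Spots with the scanner's outlier flag, 0 to 10 per array, were left out. A probe was kept when it was called well above background on both arrays of at least 1 group, which left 17004 probes and 7814 features. Of these features 3254 were coding, 1725 internal, 1348 antisense, 762 intergenic or other, 680 UTR and 45 tRNA or rRNA. A feature's value was the mean of its kept probes. Where no array of a group was well above background, or a feature lay under an array's floor there, the change is given as a lower bound of the fold. The bound sets the mean of the brighter group against the dim group's signals raised to each array's floor, the lowest signal called well above background there. It holds for the processed signal as scaled here, and another background treatment can give a smaller fold. No spot was saturated. For arrays the number of replicates limits the precision.

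A model with 4 group means was fitted in R 4.3.3 with limma 3.58.1 (lmFit, eBayes), with tables read by the package data.table (1.17.8). The comparisons were the mutant against WT in blue light, the same in green light, the difference between these strain effects (interaction), and blue against green light in WT and in the mutant. The p values, two-sided, were adjusted by Benjamini-Hochberg over the 7814 features, and an adjusted p under 0.05 counted as passing. In the text "rose", "fell" and "changed" are used for features that passed. Errors of log2 fold changes are limma's standard errors (SE). The residual degrees of freedom were 4, with prior degrees of freedom of 2.85.

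Lists of 315 genes were drawn up in 25 groups: type IV pilus machinery, minor pilins and their operons, chemotaxis-like systems, the cAMP receptor protein with Hfq and their targets, c-di-GMP turnover proteins, photoreceptors, phycobilisome, photosystem I, photosystem II, cytochrome b6f with soluble carriers, ATP synthase, tetrapyrrole and chlorophyll synthesis, inducible carbon uptake, Rubisco and carboxysome, flavodiiron proteins, nitrogen assimilation, phosphate uptake, iron limitation, heat shock proteins, high-light-inducible proteins with sigma factors, sugar catabolism and glycogen, terminal oxidases, hydrogenase, a ribosomal protein cluster and an exopolysaccharide cluster of a plasmid (pSYSM). The array held no gene of the last list, so 24 lists with 294 genes were tested. Counts are given over all features and, where they differ, adjusted over the list alone. Lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, and with fry. The p value of fry asks whether a list's genes move on balance one way, and its mixed p value whether they change in either direction. Neither sets the list against other genes.

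The genes named in the text were chosen by rule. They are sll0821 in both strain comparisons and, among coding genes that passed, those with the largest rises and falls: 10 each for the strain in blue light and for the light in WT, and 6 each for the other comparisons. Non-coding features with the largest change were 4 for the strain in blue light and for the light in WT, and 2 elsewhere. Each list adds up to 4 members with the smallest adjusted p. A further 8 genes were reported whatever their values in the strain comparisons within blue and green light (sll1694, slr1456, slr1928, slr2015, slr2018, sll1371, slr1667 and slr1143). These 8 genes and the minor pilin list were set down with knowledge of what had been published on this mutant, so they are not independent evidence. The same holds for the cAMP receptor protein list, which contains slr1667 and sll1371. The rule, the lists and the alternatives were fixed before the data were examined. Features outside the rule are named as chosen after their values were seen.

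The steps were tested on simulated data with 200 changed genes, 50 at each size. For the strain in blue light 36% of genes changed by log2 0.5 were recovered, 96% at 1, 98% at 2 and 100% at 3. For the strain in green light these shares were 26%, 94%, 100% and 100%, for the interaction 16%, 80%, 98% and 98%, for the light in WT 42%, 94%, 100% and 100%, and for the light in the mutant 32%, 90%, 100% and 100%. No recovered gene had the wrong direction. Among unchanged features, 7, 11, 10, 7 and 13 were called falsely in these runs, in the order given. In 20 runs without any effect at most 2 features were called. A ribosomal list shifted by log2 0.5 in the blue strain comparison was recovered with no other list called. Simulated genes varied independently of each other, whereas this list had an estimated correlation of 0.517 in the data. The run therefore cannot show how often camera at its preset correlation calls correlated lists falsely.

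Alternatives were background correction by normexp with offset 50, quantile normalisation, scaling to the median, normexp with quantile normalisation, the deposited table, no filter on dim probes, a filter for probes above background on all 8 arrays, outlier spots kept, the brightest probe per feature, eBayes with trend and robust, replicate number as a block, only the 4 arrays compared, changes of at least 2-fold, adjustment over coding genes alone, and each array left out in turn. Leaving out spots with the scanner's background flag was added after the data were seen, as was a comparison of each list's light change with the median of coding genes of like mean signal, in 20 bins. Slide as a random block could not be fitted as a separate term, since each slide holds 1 light. The gene table of the reference matched 0 of the array's feature names, so no coordinates are given and features carry the names of the array.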

Results

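Transcripts of WT and Δcph2 cells were compared after 48 h in blue or green light, with 2 arrays in each of 4 groups. In blue light 72.3% and 84.7% of spots were well above background in WT, and 81.2% and 86.3% in the mutant. In green light the shares were 58.1% and 72.7% in WT, and 63.3% and 59.8% in the mutant. The median signal per array ran from 1225 to 1894 intensity units. Across features, which are not independent of each other, replicates correlated with r of 0.994 in WT in blue light, 0.994 in the mutant in blue light, 0.989 in WT in green light and 0.997 in the mutant in green light. All arrays of 1 group lay beyond all arrays of the other for each feature called in a comparison of 2 groups, 162 for the strain in blue light, 17 for the strain in green light, 4277 for the light in WT and 4197 for the light in the mutant. The selection of called features favours such a separation, which by chance holds for 33.3% of features of any kind at this size, so the counts only give how many arrays show each direction.

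The transcript of the deleted gene sll0821 fell in the mutant in both lights. In blue light it was at least 9.08-fold lower (log2 fold change -3.37 ± 0.12 SE, n = 2 arrays per group, adjusted p = 1.3e-05), with a level of -1.68 in WT and -5.05 in the mutant, as log2 against the array's 75th percentile. In green light it was at least 3.0-fold lower (log2 fold change -2.75 ± 0.12, adjusted p = 0.000177), the mutant not being well above background. All 10 features named after sll0821 fell in blue light and 9 of them in green light. The labels do not give which part of sll0821 was deleted, and probes outside that part check nothing about the deletion.

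The mutant against WT in blue light addresses which transcripts depend on Cph2 in the light in which, per the design text, c-di-GMP rises in WT alone. In the mutant, slr1667 and slr1668, a pair of minor pilin genes and 4 genes of a chemotaxis-like cluster rose, while 4 genes of another minor pilin operon fell. slr1667, a target of the cAMP receptor protein, rose 35.2-fold (log2 fold change 5.14 ± 0.19 SE, n = 2, adjusted p = 1.37e-05), from -2.27 to 2.87, and its neighbour slr1668 rose 8.80-fold (3.14 ± 0.23, adjusted p = 0.000477). The minor pilin gene slr1928 rose 12.4-fold (3.64 ± 0.08, adjusted p = 3.3e-06) and slr1929 rose 7.70-fold (2.94 ± 0.09). The operon of slr2015, slr2016, slr2017 and slr2018 fell by 1.40 ± 0.09, 1.44 ± 0.09, 1.60 ± 0.11 and 1.46 ± 0.09 on the log2 scale, with an adjusted p of 0.000362 for slr2017. The genes slr0366, slr0364 and sll1009 fell, at least 51.8-fold (-5.76 ± 0.31, adjusted p = 0.000112), 21.8-fold (-4.44 ± 0.25) and 7.59-fold (-2.92 ± 0.11). None of these directions changed under the other scalings. Sizes depended on the background treatment. Over all features called in this comparison the median absolute log2 fold change was 1.19. It was 1.22 with quantile normalisation, 0.80 with normexp and 0.52 with the deposited table.

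In all, 94 features rose and 68 fell in the mutant in blue light out of 7814, and 46 and 51 of them changed by at least 2-fold. Coding genes made up 44 of the rises and 21 of the falls. Further rises were those of slr0226 (2.36 ± 0.08), slr0897 (1.78 ± 0.16) and ssl3446 (1.72 ± 0.11), and slr1259 fell by 1.08 ± 0.08. ssr2786 rose by 2.73 ± 0.30 (adjusted p = 0.00472), a call lost without WT blue replicate 2 (0.0509), mutant blue replicate 1 (0.0519) or replicate 2 (0.062) and with the deposited table (0.112). slr0701 fell at least 5.31-fold (adjusted p = 0.0497), a call lost without WT blue replicate 1 (0.251) or 2 (0.189), mutant blue replicate 1 (0.198) or either mutant green array (0.101), and at 0.051 to 0.101 under other settings such as scaling to the median. Of the non-coding features, slr0366-int1 was at least 99.1-fold lower, slr0366-int2 at least 102.7-fold, NC-436 at least 68.4-fold and NC-449 at least 55.1-fold. The number of rises went from 94 to 59 and 57 without WT blue replicate 1 and 2, to 38 and 37 without mutant blue replicate 1 and 2, and to 61 without either mutant green array.

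Among the lists, 4 of 17 chemotaxis-like genes rose in the mutant in blue light (5 adjusted over the list alone), with sll1292 at 1.40 ± 0.09, sll1293 at 1.17 ± 0.09, sll1294 at 1.48 ± 0.09 and sll1296 at 1.49 ± 0.12, while 13 did not pass. The list stood higher than other genes by camera (adjusted p = 0.000157), but adjusted p = 0.725 with an estimated correlation. Of 6 genes of the cAMP receptor protein, Hfq and their targets, slr1667 and slr1668 rose and 4 did not pass (2 rose and 1 fell adjusted over the list alone). Camera gave adjusted p = 0.0162 for them, 0.0563 with the deposited table, and adjusted p = 0.725 with an estimated correlation. As this list contains slr1667, its result is not independent evidence. The receptor gene sll1371 itself was at 0.06 ± 0.11 (adjusted p = 0.903). Of 10 minor pilin genes 2 rose, 4 fell and 4 did not pass (4 rose and 5 fell adjusted over the list alone), which is not independent evidence. Their median of -0.19 and mean of 0.10 differ in sign. By fry they moved on balance one way (adjusted p = 0.0174), with no direction recorded, and changed in either direction (mixed adjusted p = 2.11e-06). Of 12 pilus machinery genes the major pilin gene sll1694 fell by 0.56 ± 0.10 (adjusted p = 0.0425) and 11 did not pass (2 rose and 2 fell adjusted over the list alone). By fry this list changed in either direction (mixed adjusted p = 1.59e-06), with adjusted p = 0.676 for a move one way. The mixed adjusted p of fry was 0.000223 for chemotaxis-like systems, 0.00011 for the cAMP receptor protein list, 0.00166 for photoreceptors and 0.00192 for sugar catabolism. For a move on balance one way, fry gave these 4 lists adjusted p of 0.0174, 0.00317, 0.0339 and 0.955. Of 14 photoreceptor genes slr1212 rose by 1.67 ± 0.15 and slr1213 by 0.76 ± 0.13 (adjusted p = 0.041), the latter at -0.13 when measured by its brightest probe or by probes above background on all arrays. slr1212 did not pass with the deposited table (0.0747) or without the filter on dim probes (0.0869). Of 20 sugar catabolism genes slr0884 fell by 0.56 ± 0.09 (adjusted p = 0.0344) and 19 did not pass. The calls of sll1694, slr1213 and slr0884 were each lost without any 1 of the blue arrays or either mutant green array, with adjusted p from 0.067 to 0.303. Other settings ended them too, such as quantile normalisation for sll1694 (0.0575), normexp for slr0884 (0.0851) and scaling to the median for slr1213 (0.0649).

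The other 18 lists had 0 of 215 genes called in this comparison by limma, with 25 at an unadjusted p under 0.05. The c-di-GMP turnover list was among them, with 3 of its 13 genes at an unadjusted p under 0.05 and a mixed adjusted p of 0.0154 by fry, and slr1143 stood at -0.16 ± 0.11 (adjusted p = 0.685). Other lists among the 18 with a mixed adjusted p under 0.05 by fry were high-light-inducible proteins and sigma factors (0.0174), heat shock proteins (0.0228) and ribosomal proteins (0.0444). All 23 ribosomal protein genes lay above the median of all features of -0.0092, with a list median of 0.21 (camera adjusted p = 3.96e-08, adjusted p = 0.725 with an estimated correlation). Hydrogenase genes had a median of -0.37 (camera adjusted p = 0.00328, adjusted p = 0.725 with an estimated correlation, 0.107 without mutant blue replicate 1). ATP synthase genes passed camera with adjusted p = 0.0241 (adjusted p = 0.963 with an estimated correlation, 0.258 without WT blue replicate 2, 0.55 without mutant blue replicate 1). Adjusted over the list alone, 3 of 8 heat shock genes were higher, and 1 hydrogenase gene of 5 and 1 of 9 high-light-inducible and sigma factor genes lower. The phycobilisome, photosystem I and II, cytochrome b6f, tetrapyrrole, carbon uptake, Rubisco and carboxysome, flavodiiron, nitrogen, phosphate, iron and oxidase lists had no gene called by limma either way. Camera passed photosystem I without WT blue replicate 2 (0.0148), cytochrome b6f without WT blue replicate 1 (0.0417) and heat shock proteins without WT blue replicate 1 (0.0375) or mutant blue replicate 2 (0.0242). It also passed photosystem II and cytochrome b6f with normexp and quantile normalisation (0.0316 and 0.0434) and with the deposited table (0.00429 and 0.00851). slr1456 stood at -0.04 ± 0.16 (adjusted p = 0.963).

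**Figure D1:**
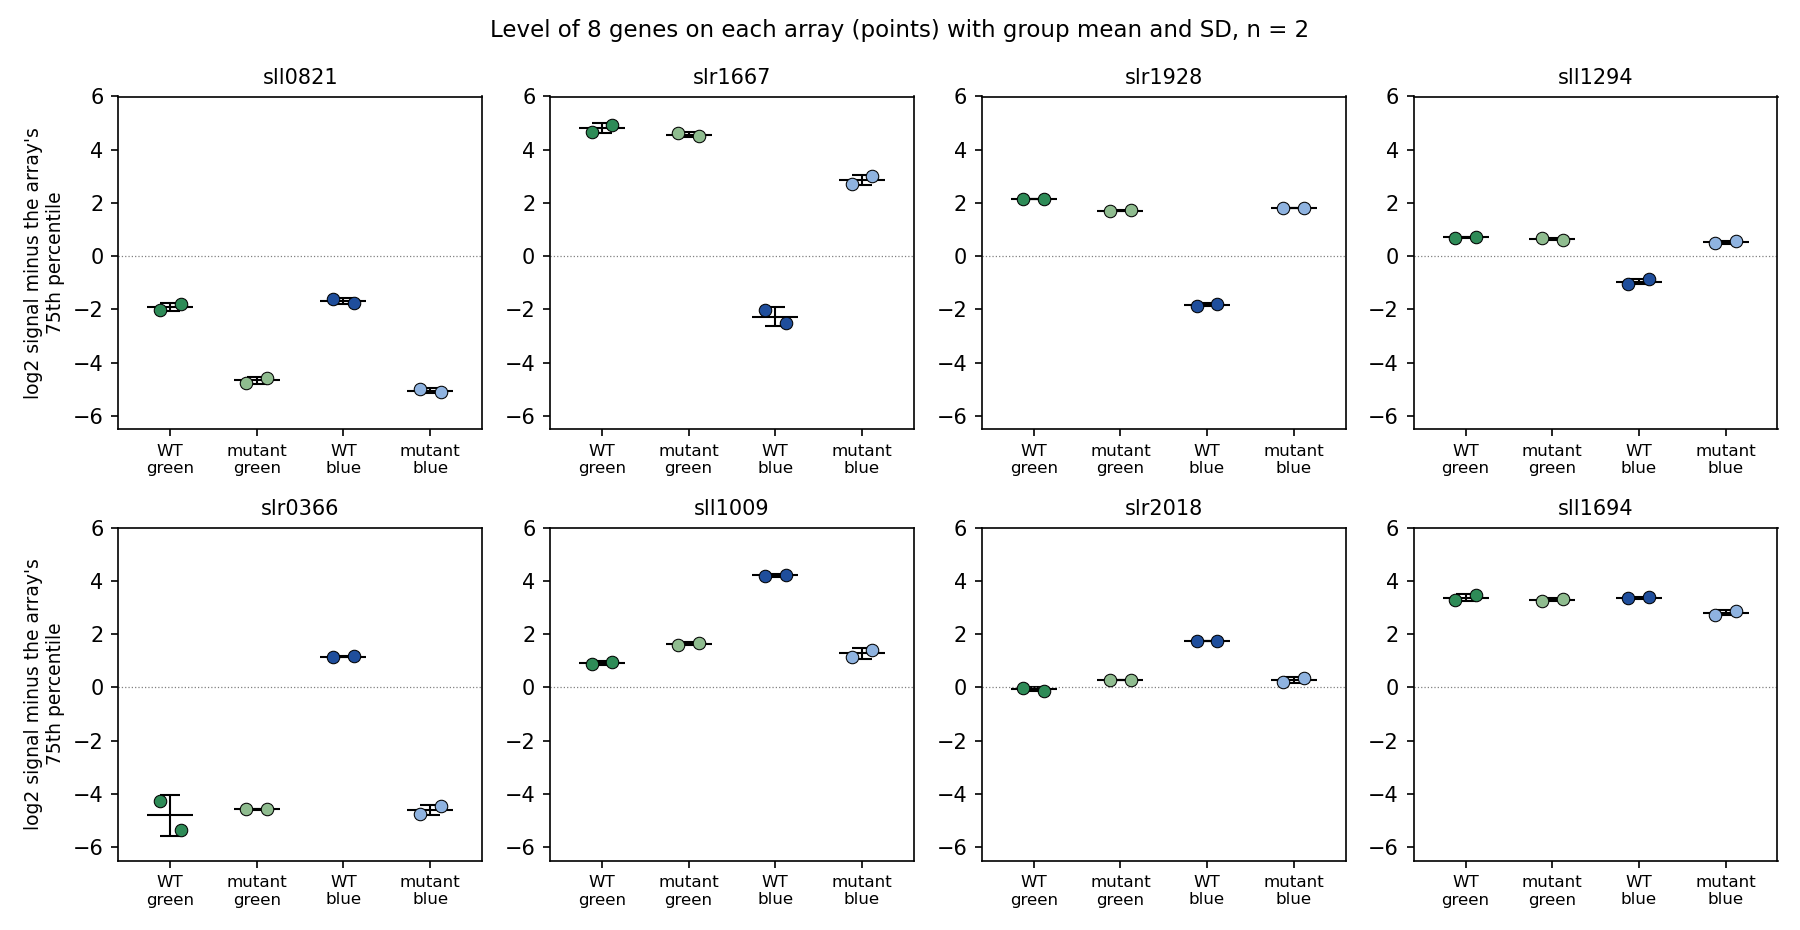
Level of 8 genes on each array, as log2 of the processed signal against the array's 75th percentile, with points for arrays and bars for group means ± SD (n = 2 per group). In blue light slr1667 averaged -2.27 in WT and 2.87 in the mutant, and sll0821 averaged -1.68 and -5.05.

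The mutant against WT in green light is the control comparison, since per the design text c-di-GMP did not differ between the strains there. Apart from the deleted gene, its antisense and internal RNAs and some intergenic transcripts, few features changed. In all, 3 features rose and 14 fell (702 at an unadjusted p under 0.05), and 9 of the 17 carry the name sll0821. NC-436 fell at least 28.3-fold and sll0821-int2 at least 21.4-fold, and the call of sll0821-int2 was lost without WT green replicate 1 (0.0612), mutant green replicate 1 (0.0535) or replicate 2 (0.0674). Named after their values were seen, NC-438, NC-447, NC-449 and slr0534-int2 fell to levels not well above background, while sll1886-as1, slr1489-as1 and slr1529-int1 rose, each at or near background in at least 1 group. The 3 rises became 0 of 16 calls with normexp, 0 of 14 with normexp and quantile normalisation and 0 of 15 with the deposited table, against 3 of 17. Without WT blue replicate 1 or 2 there was 1 rise, without mutant blue replicate 1 or 2 or WT green replicate 1 there were 0, without WT green replicate 2 there were 7, and without mutant green replicates 1 and 2 there were 1 and 0. All 13 features called in both lights fell in both, against 0.122 if the lists were independent.

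No gene reported whatever its value passed in green light. sll1694 stood at -0.08 ± 0.10 (n = 2, adjusted p = 0.844), slr1456 at -0.65 ± 0.16 (0.28), slr2015 at 0.21 ± 0.09 (0.578), slr2018 at 0.35 ± 0.09 (0.289), sll1371 at -0.02 ± 0.11 (0.977), slr1667 at -0.23 ± 0.19 (0.779) and slr1143 at 0.05 ± 0.11 (0.92). slr1928 stood at -0.44 ± 0.08 (adjusted p = 0.155) and passed with the deposited table at -0.34 (0.0111). Of 294 listed genes limma called 0, with 21 at an unadjusted p under 0.05. The mixed adjusted p of fry was 0.00228 for cytochrome b6f, 0.00602 for minor pilins and 0.0235 for iron limitation. For a move on balance one way, fry gave the iron list adjusted p = 0.0499. Adjusted over the list alone, 3 minor pilin genes were higher and 4 lower of 10, 1 cytochrome b6f gene of 10 was higher and 4 iron limitation genes of 5 were higher. Camera passed the iron list (adjusted p = 0.0017, median 0.61), the ribosomal list (0.0017), heat shock proteins (0.00896), photosystem II (0.0123) and the phycobilisome (0.0309). For the iron list adjusted p = 0.427 with an estimated correlation, and for the other 4 adjusted p = 0.804. Without WT green replicate 1 they had adjusted p of 0.145, 0.281, 0.281, 0.324 and 0.69 in that order, and without mutant green replicate 2 ribosomal proteins (0.174), photosystem II (0.297) and the phycobilisome (0.285) did not pass either. The phycobilisome result also ended with quantile normalisation (0.177), also when combined with normexp (0.13).

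**Figure D2:**
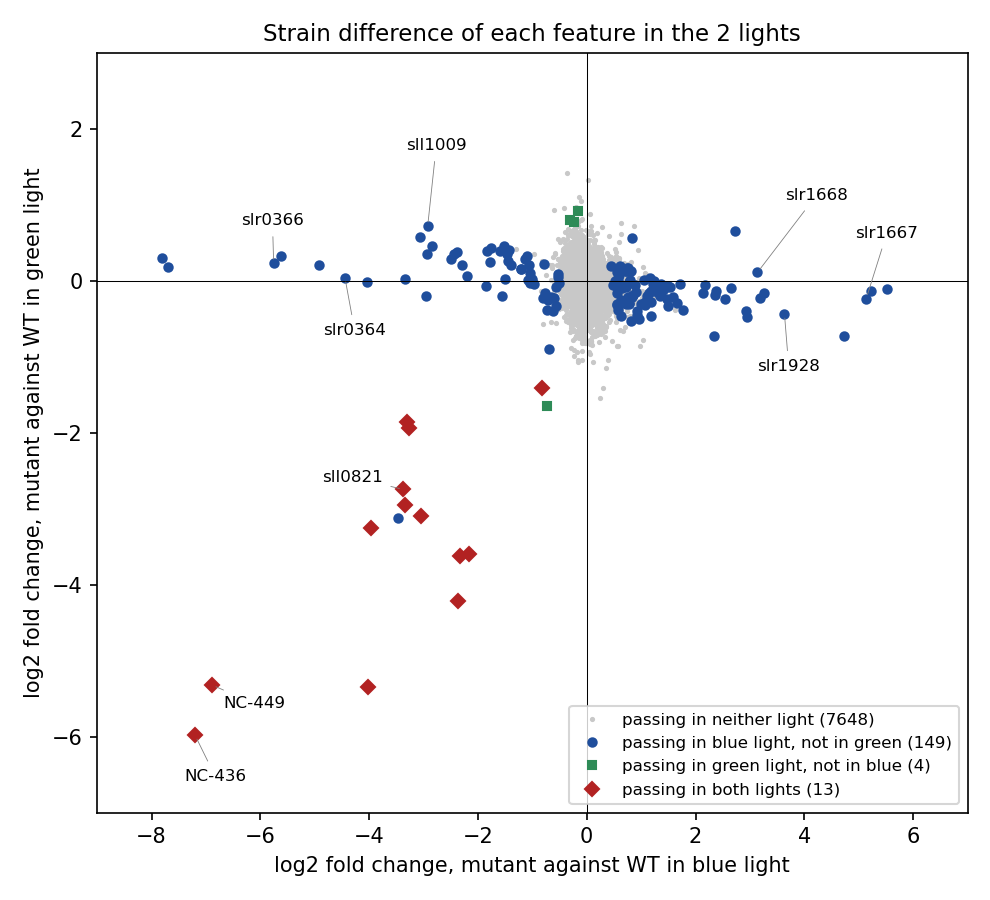
Log2 fold change of the mutant against WT in blue light (x axis) and in green light (y axis) for 7814 features, each the difference of group means with n = 2 arrays. Of these 149 passed in blue and not in green light, 4 in green and not in blue light, and 13 in both, and slr1667 lay at 5.14 in blue and -0.23 in green light.

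The interaction asks which strain effects differ between blue and green light. Each light lies on its own slide, so a strain effect that differs by slide cannot be told apart from one that differs by light. The effect of the mutation was higher in blue light for slr1667 (log2 difference 5.37 ± 0.27 SE, n = 2 per group, adjusted p = 0.000126), for slr1928 (4.07 ± 0.11, adjusted p = 2.66e-05), slr1929 (3.42 ± 0.13) and slr1668 (3.03 ± 0.32). It was lower in blue light for slr0366 (-5.99 ± 0.45, adjusted p = 0.00107), slr0364 (-4.48 ± 0.35) and sll1009 (-3.64 ± 0.16), the first 2 not well above background in green light in either strain, so that the size of their difference is not exact, and for slr2015 to slr2018, with -1.61 for slr2015 and -1.99 ± 0.16 for slr2017. In all, 64 features were higher and 41 lower, of which 30 and 11 were coding genes. Of the 105, 97 were also called for the strain in blue light, against 2.18 if the lists were independent. Both comparisons use the same blue arrays, so their overlap is not independent evidence. Across features they correlated with r of 0.805, against 0.705 in simulated data without an effect. The count of 64 went to 42 and 33 without mutant blue replicate 1 and 2, and to 41 and 29 without mutant green replicate 1 and 2, while 41 went to 27 without mutant green replicate 2.

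Of the lists, 4 of 17 chemotaxis-like genes had a higher effect in blue light (5 adjusted over the list alone), such as sll1296 with 1.56 ± 0.17 and sll1294 with 1.56 ± 0.13. Camera gave adjusted p = 0.00691, and adjusted p = 0.826 with an estimated correlation, and without WT green replicate 2 it gave 0.0589. Of 10 minor pilin genes 2 were higher and 4 lower (5 and 4 adjusted over the list alone), with a median of 0.12, a mean of 0.19 and a camera direction of down (adjusted p = 0.977), the median changing sign under 2 other scalings. Of the cAMP receptor protein list 2 of 6 genes were higher (2 higher and 1 lower adjusted over the list alone), which is not independent evidence. Camera gave adjusted p = 0.0454 for it, and adjusted p = 0.534 with an estimated correlation. Photosystem I had no gene called by limma and adjusted p = 0.0454 (adjusted p = 0.826 with an estimated correlation), and hydrogenase no gene called and adjusted p = 0.0445 (adjusted p = 0.876 with an estimated correlation). The cAMP list, photosystem I and hydrogenase were lost without WT blue replicate 1 (0.157, 0.32 and 0.157), mutant blue replicate 1 (0.0529, 0.0783 and 0.121), WT green replicate 1 (0.119, 0.161 and 0.161), WT green replicate 2 (0.0589 for each) and mutant green replicate 1 (0.0594, 0.0502 and 0.0594). The cAMP list and photosystem I were lost without mutant blue replicate 2 too (0.0726 for both), and photosystem I without mutant green replicate 2 (0.141) and with quantile normalisation (0.712). The cAMP list was lost with quantile normalisation (0.0696), also when combined with normexp (0.0503), and with the deposited table (0.0704). The ribosomal list passed camera without mutant blue replicate 2 (0.00613) or mutant green replicate 2 (0.0247), and the iron list without mutant green replicate 1 (0.00872). Both also passed with quantile normalisation (0.0488 for each), and the ribosomal list with normexp and quantile normalisation (0.0088) and with the deposited table (0.000694). Of 14 photoreceptor genes slr1212 was higher (1.96 ± 0.21), a call lost with normexp (0.0949), the deposited table (0.163), no filter on dim probes (0.282) and the brightest probe (0.0792). In the other 20 lists limma called 0 of 247 genes, with 19 at an unadjusted p under 0.05, and adjusted over the list alone 2 pilus machinery genes were higher and 1 lower, 1 cytochrome b6f gene was lower and 1 phosphate uptake gene higher. Pilus machinery had a mixed adjusted p of 4.56e-06 by fry, and adjusted p = 0.616 for a move on balance one way. For minor pilins these values of fry were 5.93e-06 and 0.039.

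Blue against green light in WT addresses the response to the light that, per the design text, raises c-di-GMP, and the light and the slide cannot be told apart in it. Transcripts of slr0366, slr0364 and sll1009 rose in blue light, while slr1667, slr1668, slr1928, slr1929, sll0450, the gene of a nitric oxide reductase, and genes of a CRISPR-associated region of the plasmid pSYSA fell. slr0366 rose at least 31.1-fold, slr0364 at least 17.1-fold and sll0310 at least 14.0-fold, being dim in green light, and sll1009 rose by 3.28 ± 0.11 on the log2 scale (n = 2). The log2 fold change was -7.07 ± 0.19 for slr1667, -4.55 ± 0.23 for slr1668, -3.97 ± 0.08 for slr1928, -3.95 ± 0.22 for sll7086, -3.68 ± 0.30 for ssr2786, -3.33 ± 0.09 for slr1929 and -3.01 ± 0.09 for sll0450. The further falls were those of sll7085 (-2.88), sll7089 (-2.62) and sll7087 (-2.53). Of non-coding features, slr1667-int2 (-7.20) and slr1667-5'UTR (-6.36) fell, and slr0366-int1 and slr0366-int2 rose at least 47.2-fold and 48.9-fold. The further rises were those of sll0678 (at least 8.40-fold), slr7052 (at least 4.47-fold), slr0701 (at least 3.61-fold), smr0012 (at least 5.50-fold), sll0784 (at least 5.90-fold) and slr0946 (at least 5.55-fold), and without the filter on dim probes these 6 did not pass, with adjusted p from 0.0552 to 0.609.

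In WT 2876 features rose and 1401 fell in blue light, 1256 and 200 of them by at least 2-fold. Coding genes gave 1059 rises and 675 falls, antisense RNAs 843 and 69 of 1348, and 44 of 45 tRNA or rRNA features rose. The balance of coding genes turned round under most other scalings. They gave 698 rises and 849 falls with quantile normalisation, 857 and 938 with scaling to the median, and 709 and 827 with normexp and quantile normalisation. With the deposited table these counts were 724 and 816, and with normexp 801 and 733. The median of all features was 0.136, and 0.0225 when arrays were scaled to their medians. Rises made up 67.2% of calls, against 55.5% with quantile normalisation, 55.8% with scaling to the median, 55.7% with normexp and quantile normalisation, 55.5% with the deposited table and 60.2% with normexp. With probes above background on all arrays they made up 51.0%, with 1545 rises and 1487 falls. Antisense RNAs had 583 rises and 100 falls with the deposited table. Of the tRNA or rRNA features 4 passed as higher with quantile normalisation, 5 with normexp and quantile normalisation and 8 with the deposited table.

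Genes of photosynthesis, energy metabolism and protein synthesis lay mostly lower in blue light in WT, relative to the median of all features, but so did bright coding genes of any kind. Among coding genes above background on all arrays 19.4% of WT calls were higher in the brightest tercile, against 56.1% in the dimmest. Against coding genes of like signal, the list medians were -0.42 for heat shock proteins, -0.24 for ribosomal proteins, -0.15 for sugar catabolism, -0.14 for ATP synthase and for tetrapyrrole synthesis, -0.04 for photosystem I, -0.02 for Rubisco and carboxysome and 0.11 for photosystem II. They were 0.0049 for cytochrome b6f and 0.14 for the phycobilisome. All 23 ribosomal protein genes fell, such as ssl3436 (-0.78) and sll1821 (-0.63), with 18 to 23 falling across scalings. Of 9 ATP synthase genes 9 fell, such as sll1326 (-0.53) and sll1324 (-0.59), with 5 to 9 across scalings. Of 12 photosystem I genes 9 fell, such as smr0005 (-0.78), and of 27 photosystem II genes 12 fell and 1 rose, slr1181, a copy of the D1 gene (at least 1.71-fold), with 8 to 16 falls across scalings. Of 20 sugar catabolism genes 11 fell, such as slr0884 (-1.15) and sll1196 (-1.23), and of 24 tetrapyrrole genes 12 fell and 3 rose, such as sll1185 (-0.91) and slr1055 (-0.66). Of 8 Rubisco and carboxysome genes 5 fell, and of 10 cytochrome b6f genes 5 fell (2 to 7 across scalings) and 1 rose, slr1185 (at least 2.64-fold). Of 8 heat shock genes 5 fell, such as the chaperonin genes slr2075 (-0.99), slr2076 (-0.97) and sll0416 (-0.96). Medians relative to that of all features were -0.66 for ribosomal proteins, -0.61 for ATP synthase, -0.53 for sugar catabolism, -0.51 for photosystem I, -0.47 for Rubisco and carboxysome, -0.43 for tetrapyrrole synthesis and -0.35 for photosystem II. Camera passed each of these lists at its preset correlation, from 5.66e-10 for ribosomal proteins to 0.019 for cytochrome b6f, and none with an estimated correlation (adjusted p = 0.319 for 6 of them and adjusted p = 0.334 for ATP synthase, tetrapyrrole synthesis and cytochrome b6f with an estimated correlation). Quantile normalisation ended the camera result of photosystem II (0.116), Rubisco and carboxysome (0.116) and cytochrome b6f (0.223), the last also lost without WT green replicate 2 (0.053). Adjusted over the list alone, the counts were the same except for 7 falls in cytochrome b6f, 14 in tetrapyrrole synthesis and 6 in heat shock.

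Motility and signalling genes also differed by light in WT. Of 12 pilus machinery genes 9 fell, such as slr0161 (-0.70), slr0162 (-0.55) and sll1533 (-0.54), and of 17 chemotaxis-like genes 9 fell, such as sll1292 (-1.77), sll1294 (-1.67) and sll1296 (-1.79). Camera gave adjusted p = 0.000101 and 8.26e-05 for these lists, and adjusted p = 0.319 for both with an estimated correlation, and their medians against coding genes of like signal were -0.30 and -0.14. Of 10 minor pilin genes 5 rose, such as slr2017 (1.92) and slr2018 (1.81), and 4 fell, which is not independent evidence, with a median of 0.49, a mean of -0.06 and a camera direction of down (adjusted p = 0.873). Of 13 c-di-GMP turnover genes 7 rose, such as slr2077 (1.80) and slr1143 (1.04), and 2 fell. Of 14 photoreceptor genes 4 rose and 5 fell, such as slr1212 (-2.15) and sll1473 (-1.25), and of 6 genes of the cAMP list 3 rose and 3 fell. Of 15 phycobilisome genes 5 fell, such as the linker gene sll1471 (-2.03) and slr0335 (-0.49), and 2 rose, with 4 to 10 falls and 0 to 2 rises across scalings. Camera gave adjusted p of 0.346 for c-di-GMP turnover, 0.134 for photoreceptors, 0.232 for the cAMP list and 0.0608 for the phycobilisome, the last passing without WT blue replicate 1 (0.0245) or WT green replicate 1 (0.0106) and with quantile normalisation (0.0121).

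In the remaining lists, 7 of 11 phosphate uptake genes rose in WT in blue light, such as slr1248 (at least 4.01-fold) and slr1250 (1.78), and 1 fell. Of 15 nitrogen genes 3 rose and 3 fell, such as the glutamine synthetase gene slr1756 (-0.75), and 1 and 3 passed adjusted over the list alone. Of 12 carbon uptake genes 4 rose, such as slr0040 (at least 2.09-fold), and 2 fell (3 and 2 adjusted over the list alone), of 9 high-light-inducible and sigma factor genes 4 rose, such as ssl2542 (at least 1.79-fold), and 2 fell, such as sll1689 (-1.38). Of 5 iron limitation genes 3 fell, such as slr0513 (-1.55) and sll1878 (-0.59), and 1 rose. Of 6 oxidase genes 3 fell, such as slr1136 (-1.18) and slr1138 (-0.97), and 1 rose. Of 5 hydrogenase genes 2 rose, such as sll1226 (0.91), and of 3 flavodiiron genes 1 rose. None of these 8 lists passed camera, with adjusted p from 0.0956 for oxidases to 0.99 for carbon uptake, though oxidases passed without WT blue replicate 2 (0.0391). The call of sll1226 was lost without the filter on dim probes (0.232). The median of the carbon uptake list changed sign under 3 other scalings, that of nitrogen under 2 and that of the high-light-inducible list under 1. Across scalings 3 to 7 phosphate uptake, 0 to 4 nitrogen and 1 to 4 carbon uptake genes rose.

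**Figure D3:**
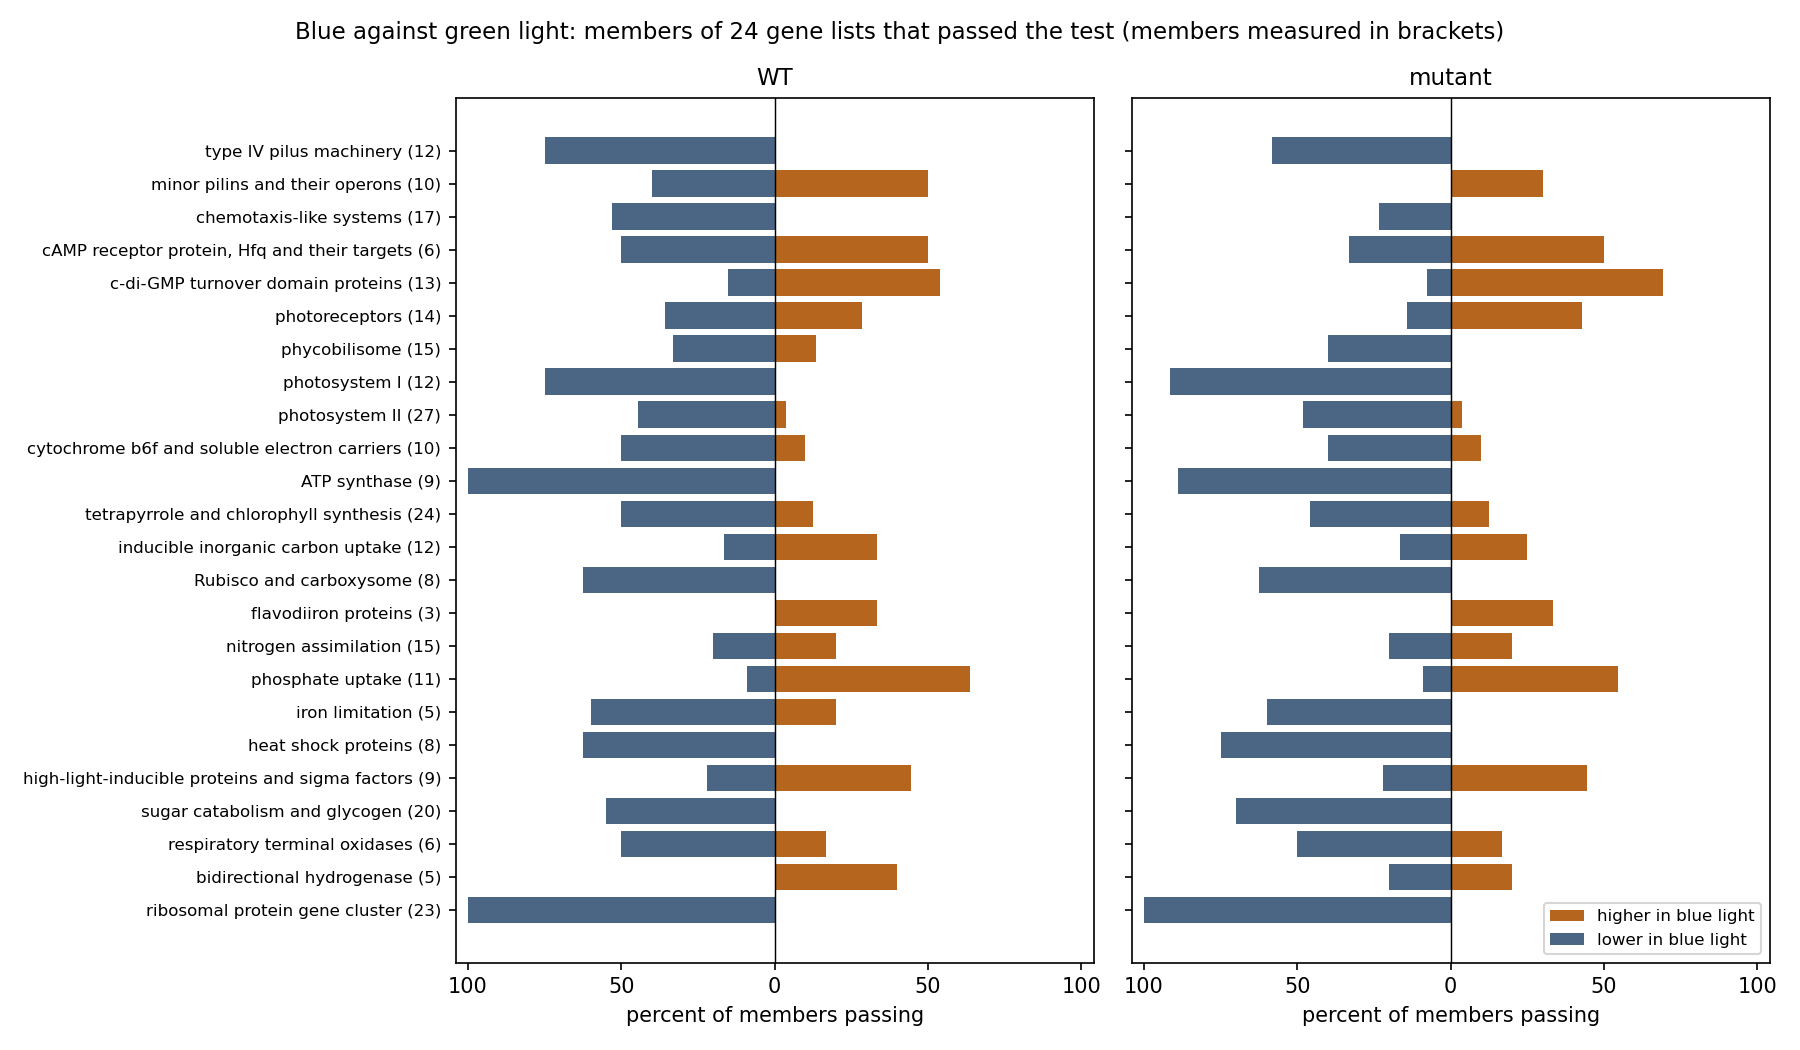
Percent of each gene list's members that passed as higher or lower in blue against green light, in WT and in the mutant, from limma with n = 2 arrays per group. All 23 ribosomal protein genes were lower in both strains as scaled here, with 18 to 23 lower in WT and 7 to 23 in the mutant across scalings.

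Blue against green light in the mutant asks which light responses remain without Cph2, with light and slide again confounded. sll0450 and CRISPR-associated genes fell here too, while slr1667 and slr1668 fell by less than in WT, a difference that the interaction test passed. The log2 fold change was -3.06 ± 0.09 for sll0450 (n = 2), -2.86 ± 0.22 for sll7086, -2.21 for sll7089, -2.20 for sll7067, -2.16 for sll7085 and -2.23 ± 0.26 for slr0301. slr1667 fell by 1.70 ± 0.19 and slr1668 by 1.52 ± 0.23. slr1214, a response regulator gene, rose by 3.81 ± 0.46, with a spread of 1.01 (SD) between its mutant arrays in blue light. sll0310 rose at least 12.6-fold, sll0678 at least 7.22-fold, sll1874, an enzyme of chlorophyll synthesis, at least 3.94-fold, slr7052 at least 2.69-fold and slr1248 at least 2.53-fold. Without the filter on dim probes sll0310 (0.177) and sll1874 (0.585) did not pass, and sll0678 and slr7052 stood at -0.06 and -0.09. The feature ssl1045-5'UTR rose at least 6.94-fold and slr1968-as3 at least 6.17-fold.

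In the mutant 3056 features rose and 1141 fell in blue light, 1162 and 131 by at least 2-fold. Coding genes gave 1132 rises and 560 falls, antisense RNAs 903 and 40 of 1348, and 43 of 45 tRNA or rRNA features rose, against 5 with quantile normalisation, 8 with normexp and quantile normalisation and 11 with the deposited table. Coding genes gave 644 rises and 679 falls with quantile normalisation, 839 and 882 with scaling to the median, and 621 and 701 with normexp and quantile normalisation. With the deposited table these counts were 618 and 718, and with normexp 752 and 615. The median of all features was 0.198, and 0.0514 with scaling to the median. Rises made up 72.8% of calls, against 61.4% with quantile normalisation, 57.1% with scaling to the median, 59.8% with normexp and quantile normalisation, 58.9% with the deposited table and 65% with normexp. With probes above background on all arrays they made up 56.2%, with 1587 rises and 1239 falls. The 1141 falls became 697 without mutant blue replicate 2, 606 without mutant green replicate 1 and 556 without mutant green replicate 2. The strains shared 2487 rises and 893 falls, against 1125 and 205 if the lists were independent, and 31 features changed in opposite directions. Across features the changes of the strains correlated with r of 0.851.

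Most of these lists also lay lower in blue light in the mutant, where 18.2% of coding calls were higher in the brightest tercile and 64.0% in the dimmest. Against coding genes of like signal the list medians were -1.02 for iron limitation, -0.41 for heat shock proteins, -0.28 for sugar catabolism, -0.25 for pilus machinery, -0.19 for photosystem I, -0.11 for ribosomal proteins, -0.01 for ATP synthase and 0.03 for photosystem II and for the phycobilisome. They were -0.13 for tetrapyrrole synthesis, -0.11 for Rubisco and carboxysome, -0.03 for chemotaxis-like systems and 0.10 for cytochrome b6f. The phycobilisome and iron lists passed camera here and not in WT, a difference that the interaction did not pass (camera adjusted p = 0.309 and 0.0595). All 23 ribosomal protein genes fell, such as sll1813 (-0.57) and sll1821 (-0.51), with 7 to 23 across scalings. Of 12 photosystem I genes 11 fell, such as smr0005 (-0.95), of 27 photosystem II genes 13 fell and 1 rose, of 9 ATP synthase genes 8 fell, such as sll1326 (-0.50), of 20 sugar catabolism genes 14 fell, such as slr0884 (-1.39) and slr1857 (-0.89), and of 24 tetrapyrrole genes 11 fell, such as sll1185 (-0.98), and 3 rose. Of 8 heat shock genes 6 fell, such as slr2075 (-0.79), of 8 Rubisco and carboxysome genes 5, of 15 phycobilisome genes 6, such as sll1471 (-1.75), and of 10 cytochrome b6f genes 4, with 1 rise. Of 12 pilus machinery genes 7 fell, such as sll1694 (-0.49), of 17 chemotaxis-like genes 4 and of 5 iron limitation genes 3, such as slr0513 (-1.97) and slr1295 (-1.38). Camera passed each of these lists, from 3e-10 for ribosomal proteins to 0.0171 for cytochrome b6f. With an estimated correlation none passed, with adjusted p = 0.29 for photosystem I as the lowest and adjusted p = 0.375 for chemotaxis-like systems as the highest. Of 6 oxidase genes 3 fell, such as slr1136 (-1.31), and 1 rose, with camera adjusted p = 0.0473 (adjusted p = 0.416 with an estimated correlation), lost without mutant blue replicate 1 (0.0581) or WT green replicate 1 or 2 (0.0646) and with scaling to the median (0.0794). Across scalings 2 to 9 ATP synthase and 5 to 20 photosystem II genes fell. The falls ran from 7 to 11 for pilus machinery, 4 to 10 for chemotaxis-like genes, 6 to 10 for the phycobilisome and 2 to 6 for cytochrome b6f. Quantile normalisation ended the result of cytochrome b6f (0.394) and of Rubisco and carboxysome (0.06). Medians relative to that of all features were -0.71 for photosystem I, -0.59 for ribosomal proteins, -0.57 for sugar catabolism and -0.54 for ATP synthase. Adjusted over the list alone, falls numbered 9 in ATP synthase, 12 in tetrapyrrole synthesis and 2 among chemotaxis-like genes, and rises 2 among oxidases.

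Of 13 c-di-GMP turnover genes 9 rose in the mutant in blue light, such as slr2077 (1.23) and slr1143 (0.82), with 3 to 9 rising across scalings, and 1 fell. Of 10 minor pilin genes 3 rose (2 adjusted over the list alone), such as slr2019 (0.79), which is not independent evidence, and the median of this list changed sign under 1 other scaling. Of 14 photoreceptor genes 6 rose and 2 fell (6 and 3 adjusted over the list alone), such as sll1473 (-1.09), with 1 to 6 rising and 2 to 6 falling across scalings. Of 6 genes of the cAMP list 3 rose and 2 fell, with a median that changed sign under 2 other scalings. Of 11 phosphate uptake genes 6 rose (7 adjusted over the list alone), such as slr1250 (1.27), and 1 fell. Across scalings 3 to 6 of them rose, and their median changed sign under 1 other scaling. Of 15 nitrogen genes 3 rose and 3 fell, such as slr1756 (-0.78), and of 12 carbon uptake genes 3 rose, such as slr0040 (at least 1.54-fold), and 2 fell (2 rose and none fell adjusted over the list alone), the medians of both changing sign under 4 other scalings. Of 9 high-light-inducible and sigma factor genes 4 rose, such as ssl2542 (at least 1.63-fold), and 2 fell, such as sll1689 (-1.67), with a median that changed sign under 1 other scaling. Of 5 hydrogenase genes 1 rose, sll1226 (0.71), and 1 fell (1 rose and none fell adjusted over the list alone), and of 3 flavodiiron genes 1 rose. The call of sll1226 was lost without the filter on dim probes (0.24). None of these 10 lists passed camera, with adjusted p from 0.165 for phosphate uptake to 0.984 for carbon uptake.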

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

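The strain effect differed between blue and green light for the results below, by the interaction test of limma. Light and slide cannot be told apart in that test. The tests on intergenic transcripts were chosen after their result was seen, and the other tests before.

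Of 7814 features 64 had a higher and 41 a lower mutant effect in blue than in green light. The log2 differences of those named were 5.37 for slr1667, 4.07 for slr1928, 3.42 for slr1929 and 3.03 for slr1668, 2.56 for slr0226, 2.16 for slr0897, 1.96 for slr1212 and 1.76 for ssl3446. In the chemotaxis-like cluster they were 1.56 for sll1296, 1.56 for sll1294, 1.52 for sll1292 and 1.31 for sll1293. Lower effects were -5.99 for slr0366 and -4.48 for slr0364, both not well above background in green light in either strain, -3.64 for sll1009, -1.99 for slr2017, -1.82 for slr2018, -1.70 for slr2016, -1.61 for slr2015 and -1.10 for slr1259. The non-coding features had -8.11 for slr0366-int1, -7.88 for slr0366-int2 and -1.56 for NC-449. These sizes are not exact, since slr0366-int1 and slr0366-int2 were well above background in WT in blue light alone, and NC-449 in neither light in the mutant, so that its value cannot be read as an effect that differs by light. Among the lists, camera's adjusted p was 0.00691 for chemotaxis-like systems, 0.0454 for the cAMP receptor protein list, 0.0454 for photosystem I and 0.0445 for hydrogenase, with adjusted p = 0.534 as the lowest with an estimated correlation, and each was lost without WT green replicate 2 (0.0589). Without mutant green replicate 2 the counts of 64 and 41 became 29 and 27.

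Genes that changed in the mutant in blue light mostly moved toward their level in green light: of the 94 rises 86 were lower in blue than in green light in WT (16.9 if independent), such as slr1667 and slr1928, and of the 68 falls 45 were higher, such as slr0366 (25 if independent). Both comparisons use the WT blue arrays, which alone favours opposite directions. Simulated data without an effect had opposite directions in 66.7% of features and 89.5% of top genes, and a correlation of -0.502 (-0.470 observed). At most 2 simulated features passed in any comparison, so the counts of features that passed in both have no like share to be set against. The covariance was -0.0125 in simulated data and -0.151 as observed, which over all features argues against shared arrays as the whole cause. With calls made on WT blue replicate 1 and the light change taken from replicate 2, 88.6% of 105 calls moved toward the green level, against 56.4% of all features, which argues against shared arrays as the whole cause, but the other way round the gap was smaller and below the bar set in advance, with 90.9% of 110 calls against 68.2%. Of the 105 calls 86.7% had a smaller light change in the mutant than in WT, against 57.8% of all features, which is consistent with Cph2 holding these genes at their blue-light level, but this test is close to the pattern itself and leaves that a hypothesis.

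NC-436, NC-438, NC-447 and NC-449 fell with sll0821 in the mutant in both lights. The longest run that their probes shared with an sll0821 probe was 8 bases, which argues against probe sequence in common. Only the 17 sll0821 probes were compared, so a match to other parts of sll0821 was not tested. All 5 kept probes of these features (100%) lay within 20 design numbers of an sll0821 probe, against 0.512% of all kept probes, so the features may lie beside sll0821 and have been hit with it. Nearness in the design alone does not decide this, since of the 66 other kept probes in that window none was at least 2-fold lower in both lights and 1, of NC-441, was in blue light. Without coordinates a deletion and a response of neighbouring transcripts cannot be told apart.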

How the results depend on the processing

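The alternatives were chosen in advance, except the removal of spots with a background flag, which was added after the data were seen. The deleted gene sll0821 passed under each alternative that gave it a value, none of its probes being above background on all arrays, from -4.00 to -0.82 in blue light and from -4.13 to -0.82 in green light. Its lower bounds of the fold thus hold only for the signal as scaled here. Features called for the strain in green light had a median absolute log2 fold change of 2.94, against 1.87 with normexp and 0.74 with the deposited table. For the interaction 370 of 374 comparisons of a named gene with an alternative kept their direction and side of the threshold, and 4 no longer passed. These 2 counts were 609 and 50 of 661 for the strain in blue light, 202 and 3 of 206 for the strain in green light, 2179 and 117 of 2302 for the light in WT, and 1905 and 138 of 2056 for the light in the mutant. For a named gene that did not pass as scaled here, kept means only that it still did not pass, whatever its direction. Most genes named for the strain in green light were of this kind, being those reported whatever their values. The 202 there mainly counts genes that stayed uncalled and is no measure of how well directions held. The cause of the changes below was not tested unless it is named.

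The strain effect in green light had its 3 rises become 0 with normexp, with normexp and quantile normalisation, with the deposited table, without the filter on dim probes, with probes above background on all arrays, with only the 4 arrays compared, at a 2-fold minimum and over coding genes alone. Its 14 falls became 0 with probes above background on all arrays, which leaves out a transcript missing in the mutant, 9 with only the 4 arrays compared and 1 over coding genes alone. The 94 rises in blue light became 61 without the filter on dim probes, 60 with the brightest probe and 46 at a 2-fold minimum. Over coding genes alone, fewer features being tested, its rises numbered 41 and its falls 19, and the interaction had 28 higher and 11 lower. The 64 higher interactions became 37 without the filter on dim probes and 37 with the brightest probe.

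For the light in WT the rises numbered 1545 with probes above background on all arrays, 1256 at a 2-fold minimum and 1051 over coding genes alone, and the falls 899 with only the 4 arrays compared, 200 at a 2-fold minimum and 671 over coding genes alone. For the light in the mutant the rises numbered 1999 with the deposited table, 1587 with probes above background on all arrays, 1162 at a 2-fold minimum and 1128 over coding genes alone, and the falls 1753 with scaling to the median, 131 at a 2-fold minimum and 557 over coding genes alone. The 2-fold minimum and the coding genes alone lower counts by construction.

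Some named genes changed sign. slr0043 in the mutant's light response stood at -0.065 with normexp, -0.10 with quantile normalisation, -0.15 with both, -0.067 with the deposited table and -0.91 without the filter on dim probes. sll0682 in the WT light response stood at -0.0081 with normexp and quantile normalisation and -0.018 with the deposited table, and slr1393 in the mutant's at -0.054 and -0.026 with these and -0.048 without the filter. Without the filter slr1512 (0.23) and sll0218 (-0.098) in WT, and sll0678 (-0.055), slr7052 (-0.094), sll1924 (-0.026) and slr0042 (-0.13) in the mutant changed sign too, and of these light reversals none passed limma in its new direction. With the brightest probe sll0267 in WT stood at -0.60 (adjusted p = 0.00869), slr1137 in WT at 0.017 and sll0834 in the mutant at 0.47, and slr1213 for the strain in blue light stood at -0.13, as it did with probes above background on all arrays.

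With each array left out in turn, the lone array of its group is assumed to vary like the others, since limma pools the spread. The strain in blue light then gave 37 to 100 rises and 46 to 70 falls, the strain in green light 0 to 7 and 10 to 20, the interaction 29 to 88 and 27 to 53, the light in WT 2190 to 2765 and 1006 to 1304, and the light in the mutant 2078 to 3311 and 556 to 1276. For sll0821 the range was -3.46 to -3.28 in blue light and -2.85 to -2.64 in green light.

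Replicate number as a block gave 74 rises and 60 falls for the strain in blue light, 1 and 14 in green light, and 52 and 40 for the interaction. Residuals of like-numbered arrays correlated from -0.0167 to 0.154 across features, with 1 of 6 pairs of groups above 0.1. That pair was WT and the mutant in blue light, so a weak pairing there is not excluded. With the block the interaction's camera result ended for the cAMP receptor protein list (0.0686) and for photosystem I (0.0663). A random block for slide was not run, since each slide holds 1 light. The share of spots well above background, 58.1% at the lowest, limits folds of features dim in green light to lower bounds.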

Other observations

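The gene groups and runs in this part were chosen after their values were seen, as was the test of bright antisense RNAs, and the other tests before. In the CRISPR-associated region of the plasmid pSYSA, 13 of 14 genes from sll7062 to sll7090 fell in blue light in WT and 13 in the mutant under each of the scalings tried, such as sll7086 (-3.95 and -2.86) and sll7064 (-2.34 and -2.13). Between the strains in blue light, sll7070 of this region rose by 0.57. Of all 91 pSYSA genes tested, 39 rose and 18 fell in WT, and 42 rose and 17 fell in the mutant.

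Some genes with neighbouring numbers changed together in the mutant in blue light. Of 13 runs with more than 1 called gene 12 moved one way, and in 1 ssr1562 (-1.06) fell and slr1564 (0.58) rose. slr1063, slr1065, slr1066 and slr1067 rose by 1.01, 1.07, 0.72 and 1.08, and slr1071, slr1072, slr1073 and slr1074 by 1.48, 1.10, 0.95 and 0.84. Of these slr1066 (adjusted p = 0.0468 by limma), slr1073 (0.0493) and slr1074 (0.0423) lay near the threshold. slr1259, slr1260, slr1261 and slr1262 fell, with -1.08, -1.0, -1.04 and -0.97, as did slr0333 (-0.74) and slr0334 (-0.81). The antisense RNAs slr1053-as1, slr1053-as2, slr1053-as3 and slr1053-as4 fell, with -2.21, -2.30, -2.44 and -2.38.

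Antisense RNAs and their coding partners were measured in 1308 pairs. In WT 887 of the antisense RNAs changed with light, and in 470 pairs both partners did, 271 in the same and 199 in the opposite direction. In the mutant 466 pairs had both changed, 302 in the same and 164 in the opposite direction. Most antisense and coding calls were higher in blue light, 92.4% and 61.1% in WT and 95.8% and 66.9% in the mutant. Unrelated partners would thus also mostly share a direction, so the counts show no link between partners. Across pairs the light changes correlated with r of -0.022 in WT and -0.017 in the mutant.

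Features higher in blue light outnumbered lower ones, with 92.4% of antisense calls in WT, and all 44 calls of tRNA or rRNA features as scaled here (4 with quantile normalisation). Among features above background on all arrays the WT balance was near even, with 1545 rises and 1487 falls. There 41.9% of coding calls and 81.2% of antisense calls were higher. That antisense RNAs were higher only because they are dim is argued against, since within bins of like signal the share of their WT calls that were higher exceeded that of coding calls by 36.8 points on average (12.4 to 80.9 across 10 bins), and by 39.0 points in the mutant (19.2 to 95.5). Dim signals scaled differently on the 2 slides are argued against for antisense RNAs, of whose WT calls 78.8% were higher in the brightest tercile of features above background on all arrays, against 81.2% in the dimmest. For all features together this explanation stays open, with 40.7% higher in the brightest tercile and 60.1% in the dimmest. That light raised antisense transcripts stays open too, since the number of slides that hold both lights is 0, and light and slide cannot be told apart.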
